A study of Mus musculus with 2 samples.

How the data were processed

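RNA of 2 mouse epithelial cell lines, named Mlesico and Mle29c in the labels, was measured on 1 oligonucleotide expression array each. Per the labels, both lines were grown in the same medium with serum, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. The array holds 45101 probe sets, each a group of short probes; some match several genes and some are controls. MAS5, a method that summarises the probes of a probe set into 1 signal, is named in the submitters' processing notes; its version is not given in the sources used here. The deposited values are on a log scale, taken here as log2, and the authors centred each probe set on the midpoint of both arrays: the 2 values of every probe set sum to 0 within 1e-06, and the median of each column is 0. The log base is not stated. Base 10 would put the widest difference at 2.09e+10-fold, while a natural log is not excluded, in which case every fold would be larger than printed. The log2 ratio used throughout is the Mle29c value minus the Mlesico value, with the direction taken from the column labels. It equals the difference of log signals, but the absolute level of a transcript was removed by the centring.

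Loss of the level matters because weak MAS5 signals vary widely. The floor at the 50th percentile of signal, fixed before the data were examined, could not be applied. In its place, chosen after the data were seen, a level class was recovered from the rounding of the numbers, since single precision stores larger logarithms in coarser steps. A mean log2 level of 8 or more (signal of 256 or more) was called high, 4 to 8 middle and below 4 low. The class came from the sum of both values where its size fell in a range set for a class. Other sums, including those of exactly 0, were classed from the rounding step, and probe sets with both values at 0 were called tied. On simulated data, 96.7% of the classes from the sum and 72.8% of those from the step were right. By class, 74.3% of high, 90.7% of middle and 94.6% of low calls were right, and 6.72% of probe sets called high or middle were truly low. On the real arrays, 83.3% of 114 probe sets for ribosomal proteins and 88.9% of 81 for NADH dehydrogenase genes were in the high class, against 8.75% of 80 for olfactory and vomeronasal receptors. The low class held 10707 probe sets, of which 57.1% differed by 2-fold or more, against 13.2% of the 19946 in the high class. The high class was uneven: 5.47% of the 6824 probe sets classed from the sum were past 2-fold, against 17.2% of the 13122 classed from the step. In the middle class the share was 22.3%.

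Apart from 64 array controls, probe sets were named through the platform annotation of 2016: 34945 probe sets list a single gene, 932 list several and 9160 list none here. Symbols were updated by gene number through a gene table of the GRCm38.p6 assembly, in which 34741 of the 34945 were found; the other 204 kept the annotated symbol. The same table gave each gene's chromosome and start position, from which the order of neighbouring genes and the local gene density were taken. A gene was called measured when at least 1 of its probe sets was in the high or middle class, which held for 14961 of 18193 genes, and its value was the median log2 ratio over those probe sets. The other 3232 genes had only low or tied probe sets and were left out. No column of per-sample values was left unused.

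With 1 array per line there is no spread between replicates, so no test across replicates was possible and no p-value is given. The number of arrays limits the precision. Genes were counted by size alone, at 2-fold. As a technical measure of error inside the arrays, the SD between the log2 ratios of different probe sets of a gene was pooled over 6981 genes with 2 or more measured probe sets. It leaves out differences between cultures. The median of each of 26 gene lists, fixed before the data were examined, was set against 10000 random lists of the same size, matched on level class and number of probe sets, and its percentile describes these 2 arrays only. A list was called shifted when its percentile was below 2.5 or above 97.5; chance puts 1.3 of 26 lists there. Medians of chromosomes were set against 1000 shuffles of the genes, and their 95% intervals came from 2000 resamples of the genes, which are not replicates.

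Genes were named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest ratios among genes with a full symbol whose measured probe sets share their sign, up to 2 members per side of each list past 2-fold (or, where none is, the highest and the lowest member), and 14 preset genes. Its part on genes at the floor of a single array could not be run. Outside the rule, and after their values were seen, Sftpa1, Sftpb, Sftpc, Sftpd, Napsa, Etv5, Scgb1a1, Hk2, Pfkp, Aldoc, Ldha, Fasn and Ccl20 were named as well-known members of their lists. Ccnd1 and Ccnd2 were also named outside the rule, as cyclin D genes. Of the genes the rule takes, 1 is not reported here. Alternatives were no floor, leaving out probe sets shared between transcripts, centring of each array, and fold thresholds of 1.5 and 4. Chosen after the data were seen were the high class alone, the class from the sum alone, centring within level classes or chromosomes, and a requirement that all probe sets of a gene differ by 2-fold. Floors at the 40th, 60th and 75th percentiles, quantile and lowess scaling and the choice of the brightest probe set need the signal level and were not run; the planned search for miR-29 seed matches needs 3′ UTR sequences, which were not used here.

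The steps were tested on simulated arrays with 34945 probe sets in 15916 measured genes, of which 200 were changed. Of genes changed by a log2 ratio of 1.5, 89.6% were past 2-fold in the right direction, as were 95.7% of those changed by 2 and 54% of those changed by exactly 1. Among unchanged simulated genes 5.53% were past 2-fold. Of 40 unshifted simulated lists, 2 lay outside the central 95% of random lists. The simulated noise was set by hand, was independent between probe sets and left out differences between cultures. Its SD in each class was smaller than the SD between probe sets of a gene on the real arrays. That SD was 0.49 in the high, 0.80 in the middle and 1.72 in the low class. The simulated shares follow from these settings and give no error rate for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.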

Results

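Transcripts of the epithelial cell lines Mlesico and Mle29c were compared with 1 array per line. The series concerns miR-29c in lung fibrosis, with renewal and apoptosis of epithelial cells as its themes; the labels do not say whether miR-29c is raised or lowered in Mle29c cells. Every difference below is a log2 ratio of Mle29c over Mlesico, has no replicate check and carries no p-value. Among 14961 measured genes the median log2 ratio was 0.00.

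Markers of alveolar type 2 cells, genes of glycolysis and the hypoxia response, genes that restrain the cell cycle, and markers of airway cells were higher in the Mle29c array. The joint list of inflammation and hyaluronan genes had a lower median. The inflammation list lay inside its random range over high-class probe sets and with the class from the sum alone, and the airway list with every probe set kept. In all, 1306 genes (8.73%) were at least 2-fold higher in Mle29c and 1123 (7.51%) at least 2-fold lower. At 4-fold the counts were 430 and 379, and at 16-fold 77 and 65. Different probe sets of a gene had an SD of 0.65 in log2 ratio. Of 659 genes with 2 or more probe sets and a median past 2-fold, 87.9% had all of them on the same side of 0 (95% Wilson interval 85.1% to 90.1%), against 56.0% of all 6981 genes with 2 or more. The 659 were chosen by the median of the same probe sets, which favours a shared side, so the shares are no independent measure of reproducibility. A stricter rule, that each of 2 or more probe sets differ by 2-fold, left 138 higher and 99 lower genes, while 87 genes had probe sets past 2-fold in opposite directions. The counts moved with the probe sets used: high-class probe sets alone gave 774 and 646 genes, and all probe sets gave 2252 and 1980. As a measure of RNA integrity and labelling, the log2 ratio of the 3′ probe set minus that of the 5′ probe set was 0.07 for Gapdh, 0.07 for beta-actin and 0.54 for the transferrin receptor, whose 3′ and 5′ ratios were 0.15 and -0.39.

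Among the highest ratios, Tnc, which encodes the matrix glycoprotein tenascin C, had a log2 ratio of 8.28, with 8.23 and 8.33 in its 2 probe sets. Celsr1, a cadherin of planar cell polarity, stood at 8.84, the adhesion receptor gene Adgrd1 at 8.55 and Casd1, a sialic acid acetyltransferase, at 9.27, each from 1 measured probe set. Casd1 and Celsr1 were in the middle class, with centred Mlesico values of -4.63 and -4.42. If that class is right, their Mlesico level lay below 4, in the range of the low class, so these sizes are not firm. Other large ratios may share this limit. Pcolce2, an enhancer of procollagen processing, stood at 6.57 and the homeobox gene Hoxd8 at 7.05 in 2 probe sets, and Tmem181a, Tmem216, Tmem14a, Morn4 and Fbxl2 lay between 6.25 and 7.74. At the other end, Klhl13, an adaptor of a ubiquitin ligase, had a ratio of -10.32 and Xist, the noncoding RNA that coats the inactive X chromosome, -8.40, with all 3 probe sets between -9.23 and -7.57. Pxdn, a peroxidase that crosslinks collagen IV, stood at -6.99, the lysosomal protease gene Tpp1 at -6.86 in 2 probe sets, and the tetraspanin gene Tspan6 at -6.82 with probe sets at -8.82 and -4.81. Hddc2, Dcxr, B4galt4, Hook1, Rpp25, Pter and Crybb1 lay between -8.14 and -6.34. With every probe set kept, Klhl13 was at -7.80 and Casd1 at 6.39.

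Of 22 measured alveolar type 2 markers, 10 were at least 2-fold higher in Mle29c and 1 was at least 2-fold lower, with a list median of 0.75 (percentile 100 among 10000 random lists). Cebpa, a transcription factor of type 2 cell maturation, had a ratio of 3.26 and Lgi3 of 3.12, with probe sets from 1.58 to 5.04. The surfactant protein genes Sftpb and Sftpc stood at 2.13 and 1.66, while Sftpa1 stood at 0.62 and Sftpd at 0.02. Napsa, a protease that processes surfactant protein B, was at 2.25 and the transcription factor gene Etv5 at 1.94. Il33, a cytokine gene that is also in the inflammation list, stood at -2.64, and Fasn, which encodes fatty acid synthase, at -0.51; the other 20 were above 0. The median was 1.18 over high-class probe sets and 0.45 over probe sets whose class followed from the sum. Alveolar type 1 markers had 3 of 19 genes higher and 2 lower, with Ager at 2.24, Hopx at 1.72, Akap5 at -1.23 and the keratin gene Krt7 at -1.20. Their median of 0.28 was at percentile 97.53, and it was no longer outside the random range after centring within chromosomes (0.18, percentile 93.1) or with every probe set kept (0.23). Among 16 airway markers 6 were higher and 2 lower, with a median of 0.61 (percentile 99.5). Cldn10, a claudin of club cells, was at 2.94, the mucin gene Muc5b at 2.48 and the secretoglobin gene Scgb1a1 at 2.35, whereas the ciliated cell regulator Foxj1 was at -1.76 and Aldh1a1 at -3.89. With every probe set kept, the airway median of 0.47 was at percentile 96.4.

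**Figure D1:**
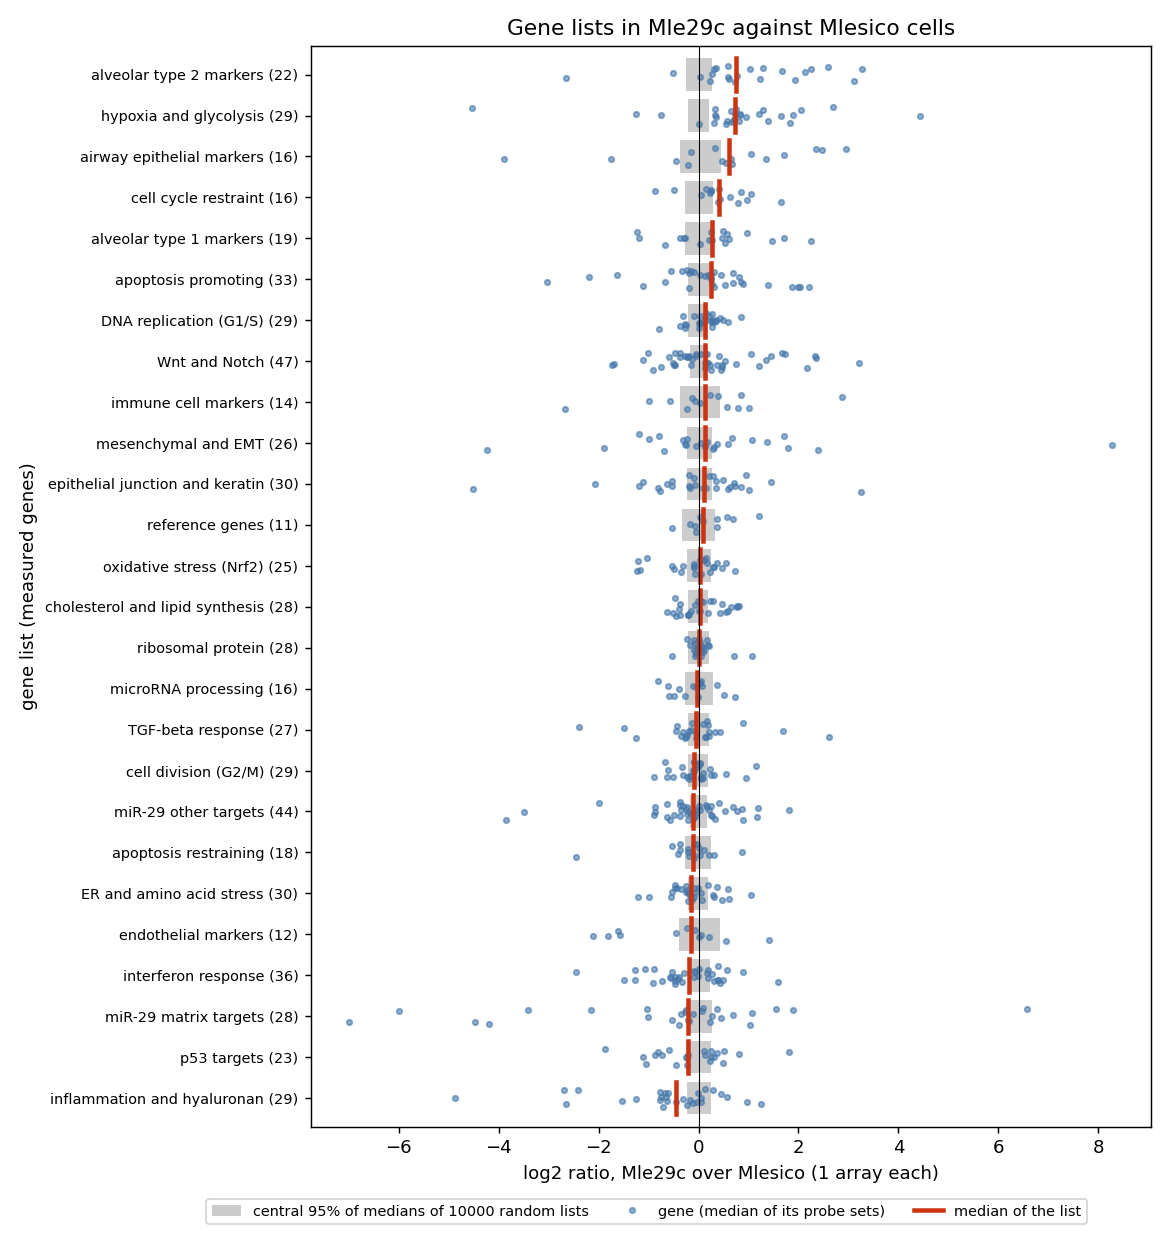
Log2 ratio of Mle29c over Mlesico (x axis, 1 array each) for the measured genes of 26 fixed gene lists (y axis, number of measured genes in brackets). Blue points are genes, red bars list medians and grey boxes the central 95% of medians of 10000 matched random lists; 6 medians lie above their box, with alveolar type 2 markers at 0.75, and 1, inflammation and hyaluronan, lies below at -0.45.

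Hypoxia and glycolysis genes had a median of 0.73 (percentile 100), with 9 of 29 at least 2-fold higher, 2 lower and 26 above 0. Ndrg1, a stress-responsive gene induced by hypoxia, was at 4.43, with its 5 probe sets between 4.27 and 4.63, and Ankrd37 was at 2.68. The glycolytic genes Hk2, Pfkp and Aldoc stood at 1.21, 1.64 and 1.83, and the lactate dehydrogenase gene Ldha at 0.35. Egln3, which encodes an oxygen-sensing prolyl hydroxylase, stood at -4.54 and Adm, which encodes adrenomedullin, at -1.25. The list medians of type 2 markers, airway markers and hypoxia genes stayed close to these values when each gene was set against the median of its chromosome, at 0.75, 0.62 and 0.70.

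The lists of DNA replication and mitosis genes differed little. They leave out the cyclin D genes Ccnd1 and Ccnd2, which are members of other lists and stood at 1.22 and 0.90. None of 29 DNA replication genes was past 2-fold (median 0.14, percentile 92.2; Mcm2 0.85, Rfc3 -0.80), and of 29 genes of mitosis only the cyclin gene Ccnb2 was, at 1.14 (median -0.08, percentile 22.3). Genes that restrain the cell cycle had a median of 0.40 (percentile 99.5), with 14 of 16 above 0 and 2 at least 2-fold higher, the antiproliferative gene Btg1 at 1.66 in 3 probe sets and the cyclin G2 gene Ccng2 at 1.04. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, stood at 0.23. Targets of p53 had 1 of 23 higher and 3 lower (median -0.22, percentile 4.35; 0.03 over high-class probe sets), with Trp53inp1 at -1.87 (probe sets at -3.04 and -0.69), the death receptor gene Fas at -1.11 and the kinase gene Plk2 at 1.80 (1.12 with every probe set kept).

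Apoptosis genes went both ways. Of 33 genes that promote apoptosis, 5 were at least 2-fold higher and 4 lower, with a median of 0.25 (percentile 98.8). Foxo1, a transcription factor, was at 2.20 with its 3 probe sets between 2.11 and 2.25, and the mitochondrial endonuclease gene Endog at 2.03, while the kinase gene Dapk2 was at -3.04 and Casp12, a caspase gene, at -2.18. This median lay inside the random range with every probe set kept (percentile 96.1), in the high class alone (97.4) and with the class from the sum alone (90.6). After centring within chromosomes it stayed outside, at 0.26 (percentile 99.5). Genes that restrain apoptosis had a median of -0.11 (percentile 22.7), with 17 of 18 within 2-fold and Birc3, an inhibitor of apoptosis, at -2.46 from 1 probe set (-1.18 with every probe set kept). Bcl2 was at 0.86, with 5 probe sets between 0.41 and 0.96, and Mcl1 at -0.12 over 6 probe sets.

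Extracellular matrix genes known as miR-29 targets were spread widely, with 5 of 28 at least 2-fold higher, 8 lower, a median of -0.21 (percentile 4.25) and a mean of -0.62. The lowest member was Pxdn at -6.99 and the highest Pcolce2 at 6.57, each from 1 probe set. Col1a1, which encodes a chain of collagen I, was at -3.41, with probe sets at -3.63 and -3.18, while Col1a2, which encodes the partner chain, was at 0.09. Col3a1 stood at 1.55, but its probe sets differed, at 0.50 and 2.59. The collagen IV genes Col4a1 and Col4a2 were at -2.15 and -1.03, the matrix protease gene Adamts9 at -6.00 in 3 probe sets, Sparc at -0.38 (probe sets from -2.31 to -0.31) and the lysyl oxidase gene Loxl4 at 1.90. Other reported miR-29 targets had a median of -0.10 (percentile 12.3), with 38 of 44 within 2-fold. The DNA methyltransferase genes Dnmt3a and Dnmt3b were at -0.49 and -0.87, Foxo3 at -0.08 (probe sets from -2.13 to 0.33), the growth factor gene Igf1 at -3.86, the T cell factor gene Tbx21 at -3.49, the lipase gene Lpl at 1.82 (probe sets at 0.81 and 2.82) and Akt2 at 1.19. Genes of microRNA processing had none of 16 past 2-fold (median -0.03, percentile 42.4; Ago2 0.72, Ago4 -0.81).

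Mesenchymal genes had 6 of 26 higher and 3 lower, including Tnc at 8.28 and Postn, which encodes periostin, at 2.39, with Fap at -4.24 and the repressor gene Snai2 at -1.89 (median 0.13, percentile 84.6). Vim, the vimentin gene, stood at 0.30 with its 3 probe sets between 0.19 and 0.37. Junction and keratin genes had 3 of 30 higher and 4 lower (median 0.12, percentile 78.7): the tight junction gene Marveld2 was at 3.24 and Cdh1, which encodes E-cadherin, at 1.46 from 1 probe set, and the splicing regulator Esrp1 was at -4.51 and the desmosome gene Dsp at -2.08. The TGF-beta response list had 2 of 27 higher and 3 lower (median -0.06, percentile 31.1), with the integrin gene Itgb6 at 2.62 (0.25 with every probe set kept), the growth factor gene Bmp4 at 1.68 and Bambi, a pseudoreceptor that dampens TGF-beta signalling, at -1.496. Tgfbi stood at -2.39 from 1 measured probe set and at 0.70 with its low-class probe sets kept. Of 47 Wnt and Notch genes 10 were higher and 4 lower, with Notch1 at 3.22, the Wnt inhibitor gene Wif1 at 2.35, the Notch ligand gene Jag1 at -1.73 (probe sets from -3.17 to -1.36) and Notch3 at -1.70; the median of 0.13 (percentile 92.4) was -0.07 after centring within chromosomes.

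Genes of inflammation and hyaluronan metabolism had a median of -0.45 (percentile 0.04), with 6 of 29 at least 2-fold lower, 1 higher and 21 below 0. Vcam1, a leukocyte adhesion molecule, was at -4.87 with its 3 probe sets between -4.98 and -3.21, the cyclooxygenase gene Ptgs2 at -2.68 and the chemokine gene Ccl20 at -2.41, whereas the hyaluronan synthase gene Has1 was at 1.25. After centring within chromosomes the median was -0.35. It was smaller over brighter or better classified probe sets, at -0.25 (percentile 3.50) in the high class and -0.05 (percentile 35.3) with the class from the sum alone. Interferon response genes had 1 of 36 higher and 5 lower (median -0.19, percentile 3.27), among them Ifitm3 at -2.44 and Gbp2 at -1.48, with Ifit3 at 1.59. Their median was -0.34 (percentile 0.30) over high-class probe sets and -0.39 (percentile 0.25) with the class from the sum alone. After centring within chromosomes it lay inside the random range, at -0.10 (percentile 14.7). Immune cell markers had 2 of 14 higher and 1 lower (median 0.13, percentile 72.0), with the scavenger receptor gene Marco at 2.88 (0.91 with every probe set kept), Itgax at -2.66 and Laptm5 at 1.02, whose probe set in the high class was at -1.60. Endothelial markers had 1 of 12 higher and 4 lower (median -0.15, percentile 20), with Pecam1 at -2.11, Sox17 at -1.81 (probe sets at -3.08 and -0.54) and Vwf at 1.40; the 6 with a high-class probe set had a median of -1.84 (percentile 0.05), outside the random range.

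**Figure D2:**
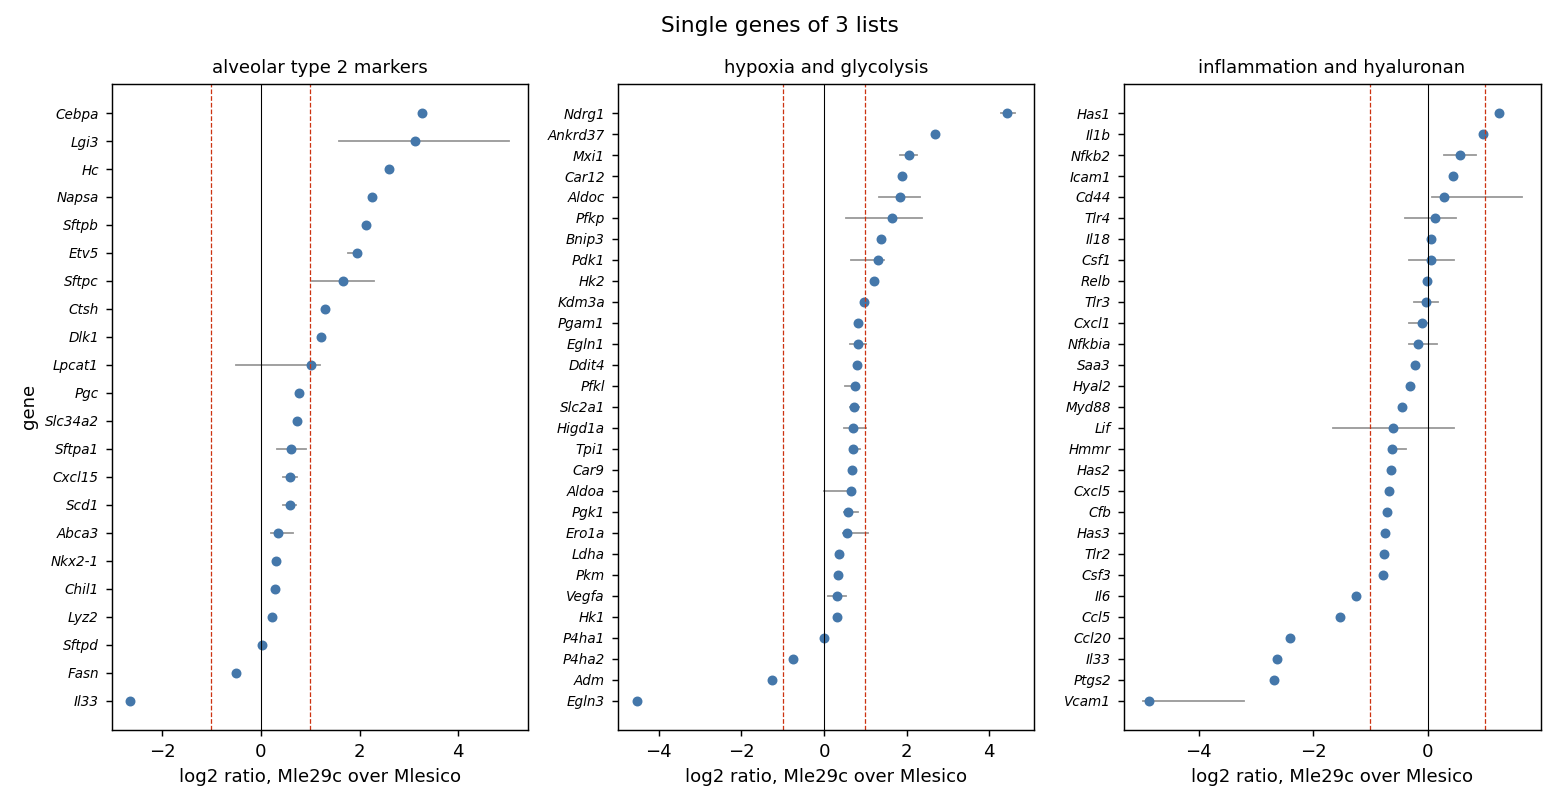
Log2 ratio of Mle29c over Mlesico (x axis) for each measured gene (y axis) of 3 lists. Points are medians over measured probe sets, grey lines run from the lowest to the highest probe set (genes without a line have 1 or near-equal ones), and dashed red lines mark 2-fold; 10 of 22 alveolar type 2 markers and 9 of 29 hypoxia and glycolysis genes lie at or beyond the upper line, and 6 of 29 inflammation genes at or beyond the lower line.

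The remaining lists lay inside their random ranges. ER and amino acid stress genes had 28 of 30 within 2-fold (median -0.14, percentile 8.53), with Nupr1 at 1.04 and the cystine transporter gene Slc7a11, which is also in the Nrf2 list, at -1.22 (-0.28 with every probe set kept). Genes of cholesterol and lipid synthesis had all 28 within 2-fold (median 0.02, percentile 62.2; 0.31 and percentile 99.5 with the class from the sum alone), from Srebf1 at -0.63 to Fads2 at 0.81. Of 25 targets of the oxidative stress factor Nrf2, 4 were lower and none higher, with Gsta4 at -1.24 (median 0.04, percentile 62.7). Ribosomal protein genes had 27 of 28 within 2-fold and a median of 0.01 (percentile 56.1), with Rpl37 at 1.07. Among reference genes 10 of 11 were within 2-fold (median 0.09, percentile 74.6), and Tbp, at 1.21, had probe sets at 0.09 and 2.33.

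Ratios also differed between chromosomes. Genes of chromosome 15 had a median log2 ratio of 0.36 (95% interval over genes 0.30 to 0.42), those of chromosome 6 of 0.32 (0.28 to 0.35), those of chromosome 19 of 0.27 (0.21 to 0.34) and those of chromosome 11 of -0.25 (-0.28 to -0.21). Chromosomes 18 and X followed at 0.11 and -0.12, and the largest chromosome median in 1000 shuffles of the genes was 0.102 in size. On chromosome 11 all 30 blocks of about 40 neighbouring genes had a median below 0, and on chromosome 6 all 19 lay above 0, as did 13 of 14 on chromosome 15 and 10 of 13 on chromosome 19. The share of genes at least 2-fold higher was 15.1% on chromosome 15 and 5.76% on chromosome 11. Of the lists outside their random range, type 1 markers had 6 of 19 genes on chromosomes 6, 15 and 19. Genes that promote apoptosis had 8 of 33 there, hypoxia and glycolysis 6 of 29, and type 2 markers 3 of 22. Airway markers had 3 of 16, inflammation genes 3 of 29 and genes that restrain the cell cycle 1 of 16. Of all 14961 measured genes, chromosome 6 held 780, chromosome 15 held 584 and chromosome 19 held 524.

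**Figure D3:**
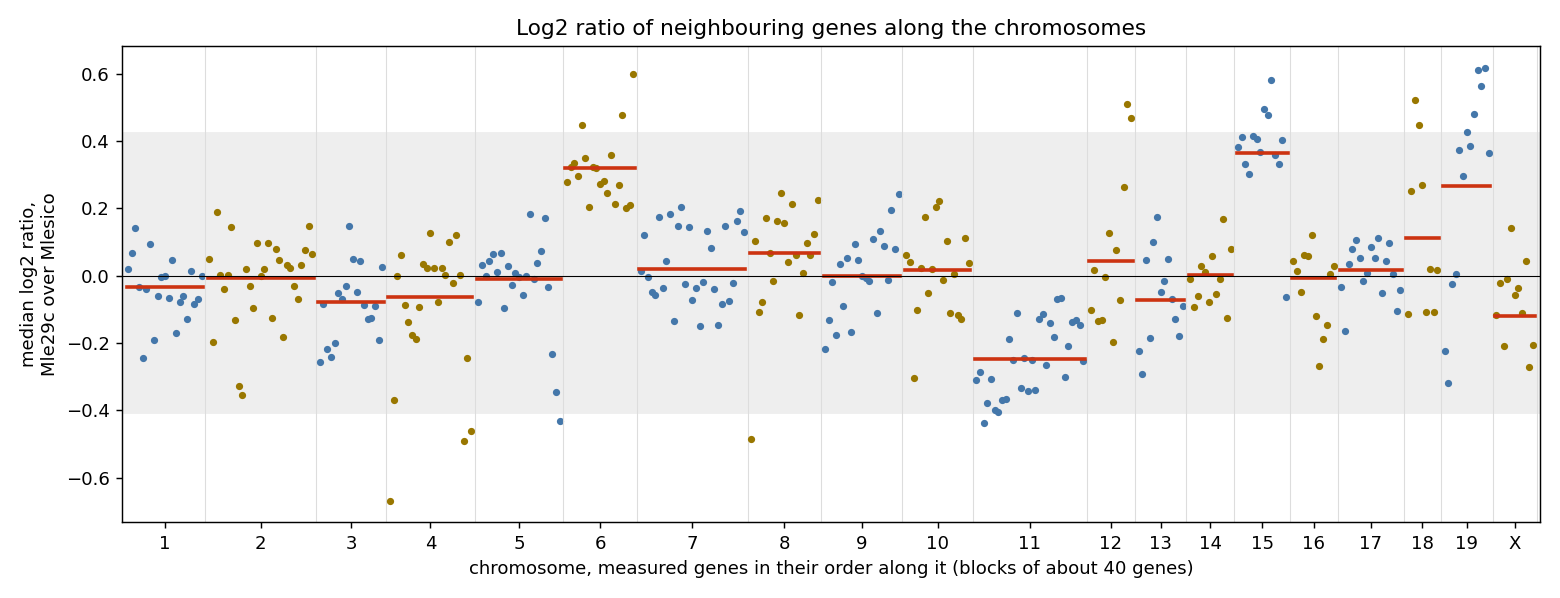
Median log2 ratio of Mle29c over Mlesico (y axis) in blocks of about 40 measured genes, in their order along chromosomes 1 to 19 and X (x axis). Points are blocks, with colours alternating by chromosome, red bars are chromosome medians, and the grey band spans the lowest (-0.41) to the highest (0.42) block in 100 shuffles; 21 of 363 blocks lie outside it.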

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

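The counts of genes depended on the probe sets and the threshold. Higher and lower genes numbered 2252 and 1980 with no floor and every probe set kept, 2524 and 2315 at 1.5-fold, and 430 and 379 at 4-fold. Among the settings chosen after the data were seen, they numbered 774 and 646 in the high class, 624 and 547 with the class from the sum, and 138 and 99 when all of 2 or more probe sets had to differ by 2-fold. Fewer genes or another threshold enter by construction. The share of genes past 2-fold whose probe sets lay on the same side of 0 was 74.9% with no floor, 91.0% in the high class and 94.6% with the class from the sum. List medians that moved by more than the SD of random lists were, with no floor, type 2 markers 0.61, Wnt and Notch 0.036, inflammation -0.60 and cholesterol 0.14. In the high class they were p53 targets 0.032, type 2 markers 1.18, type 1 markers 0.59, airway markers 1.04 (5 genes), mesenchymal genes -0.046, interferon -0.34, inflammation -0.25, cholesterol -0.092, immune markers -0.086 and endothelial markers -1.84. With the class from the sum they were type 2 markers 0.45, junction genes -0.087, interferon -0.39, inflammation -0.054, cholesterol 0.31 and immune markers -0.18. Without shared probe sets, junction genes stood at -0.063 and microRNA processing at -0.18, and centring within chromosomes put Wnt and Notch at -0.065. The cause was not tested. Hypoxia and glycolysis, cell cycle restraint and type 2 markers stayed outside their random range with no floor, in the high class, with the class from the sum and after centring within chromosomes. Of 107 named genes, Tgfbi turned from -2.39 to 0.70 with no floor and Laptm5 from 1.02 to -1.60 in the high class; the cause was not tested. With no floor 11 others moved by more than the SD between probe sets. The high class gave no value for 39 named genes and the class from the sum none for 51. Centring of each array on its median could move nothing, since both medians are 0 as deposited, and says nothing about stability. Weak signals and the single array per line both limit the values; among low-class probe sets, left out of the measured genes, 57.1% were past 2-fold. Floors at other percentiles, quantile and lowess scaling and the seed match comparison were not run. No paired analysis was possible because each line has 1 array and its replicate number is only a name.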

Other observations

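Gene families that share the start of their symbol were compared after the data were seen; 17 of 246 lay outside the central 95% of 2000 random lists each, where chance gives 12.3, so each is a lead only. The lowest percentiles were those of the Spata group (median -0.63, percentile 0.05) and the beta-defensin group Defb (-1.17, percentile 0.15), and among these 17 the highest medians were those of the prolactin group Prl (0.76), Marchf (0.53) and claudins. Olfactory receptors (Olfr) were among the 17 too (0.43, percentile 97.7). Of 64 probe sets for keratin-associated proteins and defensins, 54.7% were low-class or tied. Whether weak signals left after the level filter set such families apart was not tested. Caspase genes, also among the 17, had a median of -0.50 over 9 genes (percentile 1.5), with 2 at least 2-fold lower and none higher. The 4 families that follow were picked after their values were seen, as groups with known roles in epithelium or signalling. Claudin genes had a median log2 ratio of 0.51 over 20 measured genes, with Cldn23 at 3.78, Cldn8 at 2.68 and Cldn2 at 1.83, while 3 members were at least 2-fold lower. Dual-specificity phosphatase genes, several of which are induced by MAP kinase signalling, had a median of 0.39 over 21 genes, with Dusp5 at 2.01 and Dusp6 at 1.72. Adamts protease genes had a median of -0.59 over 10 genes, with Adamts1 at -2.11, and chemokine genes of the Ccl group one of -0.58 over 10, with 2 of these at least 2-fold higher. After centring within chromosomes these 4 medians were 0.56, 0.39, -0.77 and -0.58.

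Among genes measured by 4 or more probe sets that all differed by 2-fold the same way, picked after their values were seen, the transcription factor gene Trps1 was at 4.02 in 4 probe sets and Nr2f2 at 2.99 in 5, while Prrx1, a homeobox gene of mesenchyme, was at -2.37 in 5. Ptprg, a receptor phosphatase gene, was at -3.996 in 4 probe sets and Igf2bp3, an RNA-binding protein gene, at -1.66 in 6.

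The tests in the next 3 paragraphs were chosen after the results were seen, apart from those of gene density, of a shift of all X-linked genes and of dim probe sets.

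Chromosomes 6 and 15 stood higher and chromosome 11 lower in Mle29c along nearly their whole length, and chromosome 19 higher from block 5 of 13 on, while its lowest block stood at -0.32. A signal level that differs between chromosomes is argued against, since among high-class probe sets with the class from the sum the smallest of the 4 medians, in size, was 0.32, and so is gene density, since after centring within 10 classes of local density it was 0.25. Different copy number of long stretches of chromosomes stays open: 94.7% of the blocks on these 4 chromosomes had the sign of their chromosome, but the chromosomes were picked for their shift, so this share does not bear on it, and DNA was not measured. A further 9 blocks elsewhere lay beyond 100 shuffles, with 3 on chromosome 4 (the lowest at -0.67) and 2 neighbouring pairs, on chromosomes 12 and 18.

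Xist was at -8.40, and 10 of 11 measured genes known to escape X inactivation were also below 0, with a median of -0.64 and Jpx lowest at -1.02. Probe sets differed in sign for Firre (-0.93 to 0.49), Utp14a (-0.77 to 0.03) and Mid1 (-1.24 to 0.01). The X chromosome as a whole was slightly lower, with a median of -0.12, past the largest chromosome median in 1000 shuffles (0.102 in size). A shift shared equally by all X-linked genes is argued against only as the full account of the escape genes. The other 452 X-linked genes had a median of -0.09. The median of the escape genes was at percentile 0.40 of 10000 random sets of X-linked genes. That percentile does not exclude a smaller shift of the whole chromosome. Reactivation of an inactive X chromosome in Mle29c cells is argued against as well, as X-linked genes other than Xist had a median of -0.12, not above 0. An inactive X chromosome in Mlesico cells that Mle29c cells lack may explain the pattern, as a hypothesis that rests on the median of -0.64. A difference in the clones or passages behind the lines, unrelated to miR-29c, was not tested.

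Alveolar type 2 and airway markers were higher in Mle29c, as were hypoxia and glycolysis genes. Noise of dim probe sets is argued against for the type 2 markers, whose median was 1.18 over high-class probe sets (random range -0.28 to 0.28), where 74.3% of class calls were right in simulation, and 0.45 (percentile 99.3) with the class from the sum, where 96.7% were. The chromosome-wide shifts are argued against too, as the median was 0.75 after centring within chromosomes (-0.24 to 0.25). A difference between the 2 lines that has nothing to do with miR-29c cannot be told apart from an effect of miR-29c, because there is 1 line of each kind. Density of the cultures or medium at harvest could move hypoxia genes too and was not tested.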
